A study of Mus musculus with 8 samples.

How the data were processed

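Mouse retinas were profiled as droplet libraries. Per the labels, cells for the Chx10Cre libraries were released with papain and made into 10x 3' libraries of chemistry v3.1, the Rax libraries used chemistry v4, and nuclei for the multiome libraries were lysed with 0.01% NP40 and sorted for GFP. The submitters' processing notes list Cell Ranger, Cell Ranger ARC, Seurat, Signac and the GRCm38 build, without roles or versions; the aligner's settings are not given in the sources used here. The deposited matrices hold counts, that is whole-number UMIs per gene and barcode with no normalization, per the labels and the values. Matrices of 2 of the 8 samples were used. The Rax samples were used for their barcode and feature lists. For the multiome samples a list of barcodes, genes and peaks was used that belongs to the whole series and names no sample. Other values of these 6 samples were not analysed here. The Rax feature lists name 32287 features, 2 more than the 32285 genes of the Chx10Cre matrices, namely GFP and LOXP.

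Each sample was its own group, with 1 sample per group, as its labels name genotype, age, tissue and assay. The groups, the tests, the 16 gene lists (271 entries), the cell type markers, the rule for named genes and the alternatives were fixed before the data were examined, except where stated here.

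Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept, which removed 244 at P14 (1.85%) and 96 at P120. Scrublet's automatic threshold marked 0% and 0.0125% of barcodes, so, as planned for that case, the highest scores up to 0.8% per 1000 barcodes were taken as doublets, 1342 (10.4%) and 512 (6.40%). Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes outside the comparison lists were reduced to 30 principal components, and 15 neighbours entered joint Leiden clustering at resolution 1.0 (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15). This gave 45 clusters, numbered c0 to c44.

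Clusters were called X-like from the fixed markers where at least 3 were found in 10% of cells at 2 times the level elsewhere. Several rules of naming were set after the data had been seen: markers were scored within the library that holds most of the cluster, a cluster under its library's median UMIs with none of its own markers among its top 10 genes stayed unnamed, and so did one whose best types scored within a factor of 0.9. Scored in this way, c3 (17.0% of P14) and c5 (11.8% of P14, 0.414% of P120) had under 3 markers, as had c7, c11 and c25. The depth rule left out c43 (12.8% of P120) and the last rule c37 (0.241% and 0.120%), while c8 had a marker of another type among its top genes. Also set afterwards was a check of each cell in the Müller clusters, which needed 3 UMIs of Müller markers and no more of another type's (rod, cone and lens markers aside), and left out 10 and 27 cells. No astrocyte- or RPE-like class resulted, so the comparator planned for undeleted Sox9 is missing.

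UMIs were summed per library and cell type and given per 1000000 UMIs. Ratios are log2 of P120 over P14 with an exact conditional binomial interval, levels have exact Poisson intervals and shares Clopper-Pearson intervals, all at 95%. Genes entered with at least 20 summed UMIs, and a gene at 0 in a library was set at a floor of 3 UMIs. Classes needed 50 cells per library. For each list the members at least 1.5-fold higher or lower were counted, and its median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs. With 1 library per group, no p-value, standard error or count of changed genes was made from cells.

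The rule named Sox8, Sox9, Sox10 and Sox2; up to 4 members of each list with the largest ratios; in Müller-like cells the 10 highest and 10 lowest genes, and in rods, cones, bipolar and amacrine cells the 5 highest and 5 lowest, with at least 100 CPM, at least 2 times the level of all other cells of that library and an interval that excludes no change; and up to 10 genes at least 4-fold apart with at least 50 CPM in 5 types. Mitochondrial, ribosomal and predicted Gm genes were left out of the last parts. Named outside the rule, after their values were seen, were Gfap, the genes of clusters and of the tests in the closing section, and the lists' members that single cells carry. Which lists are given for the other cell types was also chosen afterwards, as were the counts of list members enriched in a cell type and the set of 6 crystallins.

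The steps for ratios, lists and thinning were tested on simulated data drawn from the summed profile of the P14 library for P120 against P14, with 10184 genes. Genes made 4-fold higher were recovered at a median log2 ratio of 2.00 and genes made 4-fold lower at -2.03. Intervals covered the true ratio in 95.9% of genes. No list was changed as a set, though changed genes could fall in a list, and 16 of 16 lists lay within the middle 95% of random lists. The sums were Poisson draws for well expressed genes. The coverage therefore does not test UMIs clumped in few cells or genes set at the floor.

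The alternatives set beforehand were no cell filter, a stricter filter (500 genes, 10% mitochondrial), doublets kept, each library clustered on its own, resolutions 0.5 and 2.0, thinning to 2000 UMIs or none, a total without rod and mitochondrial genes, edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors (R 4.3.3), subtraction of an ambient profile, no minimum or a minimum of 100 UMIs, and peaks within 50 kb or inside genes. Added after the data were seen were no check of single cells and Müller-like cells without the low-depth cluster. Some genes that the rule picks, and an added alternative and tests that rest on them, are not reported here. The ambient profile was the sum of each library, and its share, set by rod genes, was 37.4% and 39.4% in Müller-like, 15.6% and 30.6% in bipolar-like and 10.8% and 21.3% in amacrine-like cells; a limit of 50% set after seeing the data leaves no such value for rods, cones (100% and 100%) or microglia (32.3% and 88.0%). Peaks were set against RefSeq genes of GRCm38.p6. Figures were drawn with matplotlib 3.10.9.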

Results

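The series examined retinas of mice with a conditional knockout of the transcription factor Sox9, or of both Sox8 and Sox9, in retinal cells, and its title names the maturation of Müller glia, the radial glial cells of the retina, and the place of their nuclei as the question. It holds 8 samples, each the only sample of its group, so no difference between groups has a replicate. Of these, 4 are the RNA and the chromatin accessibility (ATAC) parts of 10x Multiome libraries from sorted GFP-positive nuclei at postnatal day 17 (P17), with GlastCreER deleting Sox8 and Sox9 in glia or not. A further pair holds whole retinas of Chx10Cre Sox9 conditional knockout (cKO) mice at P14 and P120, where the Cre acts in retinal progenitors. The last pair is RaxCreERT2 Sox8/9 cKO and control tissue at P90. Count matrices were analysed for 2 libraries, the Chx10Cre Sox9 cKO retinas at P14 and P120, so the comparison that the values allow is age within the Sox9 cKO genotype, and knockout against control was not analysed here.

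The P14 library held 13198 barcodes and 152697973 UMIs (unique molecular identifiers, each a counted RNA molecule), with a median of 4791.5 UMIs and 2232 genes per barcode. The P120 library held 8098 barcodes and 38027322 UMIs, with a median of 2445 UMIs and 1397 genes. After filtering and doublet removal, 11612 cells at P14 and 7490 at P120 remained. The barcode lists of the RaxCreERT2 Sun1GFP libraries hold 33505 barcodes for the Sox8/9 cKO and 34721 for the control. The multiome list holds 20000, all with 1 barcode suffix and no sample named, so none can be assigned to the cKO or the control. Intervals here are 95% intervals that cover counting error only.

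Sox9 RNA was present in Müller-like cells of both Sox9 cKO libraries and was far lower in every other retinal class. Müller-like cells held 496 Sox9 UMIs per 1000000 UMIs (CPM) at P14 (479 to 514; 3270 UMIs in 750 cells) and 371 at P120 (351 to 392; 1264 UMIs in 519 cells). Rod-like cells, taken as the background, held 1.86 CPM (1.38 to 2.45) and 3.57 CPM (2.12 to 5.64). Bipolar-like cells held 30.5 and 25.9 CPM, amacrine-like cells 9.05 and 12.3, ganglion-cell-like cells 5.65 and 7.05, and cone-like cells 2.51 and 1.73. Microglia-like cells had 1 Sox9 UMI at P14 and 0 at P120.

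A Sox9 UMI was seen in 42.3% of Müller-like cells at P14 (38.7 to 45.9) and in 51.8% at P120 (47.4 to 56.2), against 1.23% and 0.616% of rod-like cells. Median depths were 2823 and 5666 UMIs in Müller-like cells and 5479 and 1004 in rod-like cells. After each cell was thinned to 1000 UMIs, the Müller shares were 22.3% at P14 (19.05 to 25.78; 615 cells, 135 too shallow) and 20.8% at P120 (17.02 to 25.03; 418 cells, 101 too shallow), a difference not detectable at this depth. Without a low-depth Müller cluster, which held 400 of the 750 P14 cells and Sox9 at 46.5 CPM against 547 in the others, the shares were 36.4% and 30.8%. The thinned rod shares were 0.242% and 0.409%. Sox9 (ENSMUSG00000000567) lies on chromosome 11 at 112782210 to 112787757 of GRCm38.p6. The labels do not name the floxed exons, and a 3' tag outside the deleted part checks nothing about the deletion. No cluster was named as astrocyte- or retinal pigment epithelium-like, so the planned comparison with cells outside the Chx10 lineage was not made.

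**Figure D1:**
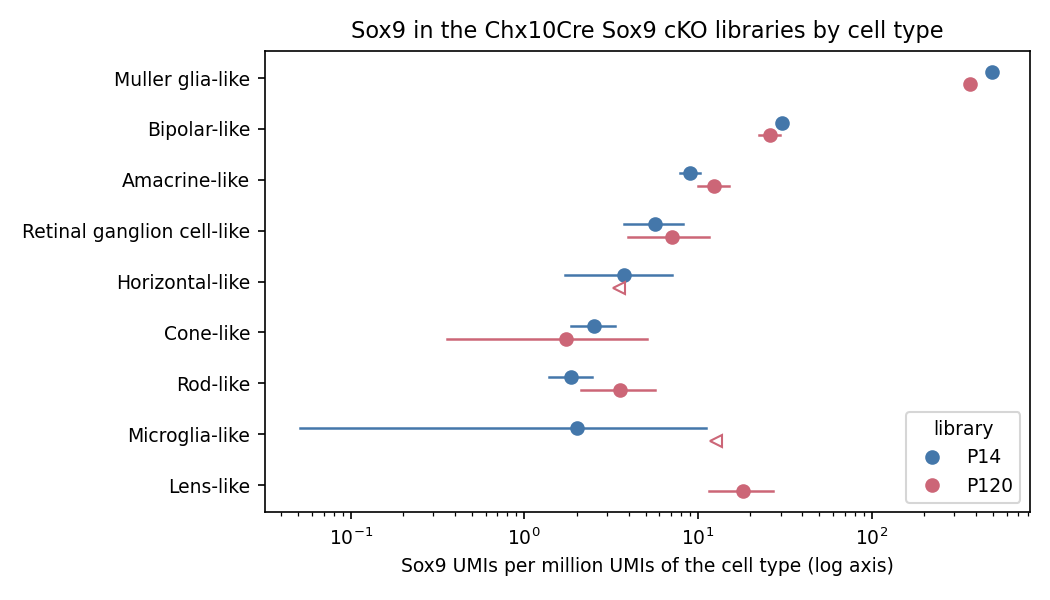
Sox9 CPM (log axis) in each cell type of the P14 and P120 Chx10Cre Sox9 cKO libraries, with exact Poisson 95% intervals; open triangles mark the limit that a count of 0 allows. Müller-like cells lie at 496 and 371, and the next retinal class, bipolar-like cells, at 30.5 and 25.9.

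The P120 over P14 ratio of Sox9 in Müller-like cells was -0.42 on the log2 scale (-0.51 to -0.32). Its size depended on how the cells were chosen: it was -0.05 under the stricter cell filter, -0.12 with the libraries clustered separately and 0.01 with doublets kept. With doublets kept, the P14 level was 325 CPM. Sox8 (ENSMUSG00000024176), the related SoxE factor, was at 94.7 CPM at P14 and 124 at P120 (log2 ratio 0.39, 0.21 to 0.57; 0.76 with doublets kept). Sox2, a progenitor and glial factor, was at 160 and 239 CPM (0.58, 0.45 to 0.71). No Sox10 UMI was seen in Müller-like cells of either library, with intervals that reach up to 0.560 CPM at P14 and 1.08 CPM at P120.

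All major retinal classes were recovered at both ages in these whole, unsorted retinas. Müller-like cells made up 6.46% of kept cells at P14 (6.02 to 6.92) and 6.93% at P120 (6.36 to 7.53), or 47.3 and 42.2 per 100 bipolar-like cells. Rod-like cells made up 28.8% (28.0 to 29.6) and 39.0% (37.9 to 40.1), bipolar-like cells 13.6% and 16.4%, amacrine-like cells 10.1% and 11.3%, and cone-like cells 4.26% and 3.55%. Ganglion-cell-like cells made up 0.887% and 1.05%, microglia-like cells 0.784% and 0.988%, horizontal-like cells 0.301% and 0.628%, endothelium-like cells 0.534% and 0.187%, and mural-like cells 0.258% and 0.0534%. Lens-like cells were 88 of the P120 cells (1.17%) and 0 of the P14 cells, with an interval that reaches up to 0.0318%.

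Clusters without a name held 33.9% of cells at P14 and 18.3% at P120, and rod markers led in the scores of their largest members, so the rod shares depend on naming. The rod share at P120 ranged from 21.0% (libraries clustered separately) to 52.2% (resolution 0.5), and the Müller share at P120 was 4.14% with separate clustering and 4.44% with no cell filter.

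Müller-like cells at P120 carried more RNA of the gliosis list than at P14 (18 of 26 members higher) and less of the progenitor list (10 of 19 lower), while most genes of mature functions lay within 1.5-fold (10 of 16). Glul, which makes glutamine from glutamate, went from 3040.6 to 7320 CPM (log2 ratio 1.27, 1.24 to 1.29), and the water channel Aqp4 from 352 to 902 CPM (1.36, 1.28 to 1.44). Folh1, a glutamate carboxypeptidase, went from 29.1 to 239 CPM (3.04, 2.81 to 3.27). In the other direction, Itm2a went from 359 to 27.3 CPM (-3.72, -4.03 to -3.42) and Hopx, an atypical homeodomain protein, from 1496 to 369 CPM (-2.02). These sums held 6590115 UMIs at P14 and 3406127 at P120, and 13692 genes reached 20 UMIs, with a median log2 ratio of -0.05. The Müller clusters were c4 (410 and 233 cells), c12 (350 and 36) and c42 (0 and 277), so that different clusters held most of the deeper cells at the 2 ages. Below, a list member counts as higher or lower from 1.5-fold, and percentiles are those of a list's median among 10000 random lists matched on expression. The alternatives counted for percentiles include a total without rod and mitochondrial genes, TMM factors and DESeq2 size factors. These shift every ratio of a cell type alike, so they cannot change a percentile.

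Of 16 measured genes of mature Müller functions, 4 were higher and 2 lower at P120 (median 0.28, percentile 98.5). Besides Glul and Aqp4, the potassium channel Kcnj10 was higher (0.78), as was Ptgds, a prostaglandin D synthase (1.57, 1.34 to 1.81), which stood at 170 CPM in all other P120 cells. Vegfa, the vascular growth factor, was lower (-0.89; -0.41 with doublets kept). The median stayed above the middle 95% of random lists in 9 of 14 alternatives, and with the libraries clustered separately the median was -0.02 and Ptgds was at -0.57.

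Of 26 measured genes of reactive gliosis and cytokine response, 18 were higher and 4 lower at P120 (median 1.47, percentile 100). Among the 18, 15 were also at least 2 times as high in Müller-like cells as in all other P120 cells together. C4b, a complement component, was seen with 0 UMIs at P14 and 31 at P120, in 18 cells. It was 19.99-fold higher with P14 set at the floor of 3 UMIs (log2 ratio 3.19 to 6.18 across settings). Serpina3n, a serine protease inhibitor, had 0 and 55 UMIs (35.5-fold higher at that floor), but from 8 cells. Timp1, a metalloproteinase inhibitor, had 0 and 31 (19.99-fold higher at that floor, log2 ratio 2.53 to 4.54 across settings), but from 4 cells. The metallothionein Mt2 was higher by 2.83 on the log2 scale (2.59 to 3.07) and A2m by 4.38 (6 cells at P120), although A2m was at 0.48 with the strict filter, 0.49 with doublets kept and 0.25 at resolution 0.5. Without Serpina3n, Timp1 and Cxcl10, each with more than 50% of its UMIs in a single cell, 15 of 23 members were higher (median 1.35). Gfap, the intermediate filament of reactive glia, chosen after its values were seen, had 18 UMIs at P14 and 62 at P120 (2.74, 1.96 to 3.58), or 18.2 CPM at P120 against 10.7 in all other cells. The same list was also higher at P120 in rod-like cells (16 of 21 members, median 2.24). Of those 16, only Fgf2 and Edn2 were at least 2 times as high as in all other P120 cells. The list was higher too in bipolar-like cells (1.15, percentile 66.7 with the ambient profile subtracted) and cone-like cells (0.69, 8 of 15 higher, percentile 99.94). Rod- and cone-like cells have no value with the ambient profile subtracted. In microglia-like cells the list was at 0.50 (percentile 99.6), and at 0.18 without Ccl2 and S100a6, which single cells carry. In amacrine-like cells it was at 0.51 (percentile 94.4; percentile 0.45 with the ambient profile subtracted).

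Of 19 progenitor and neurogenic genes, 0 were higher and 10 lower at P120 (median -0.63, percentile 0.125). The proneural factor Neurog2 was lower (-3.70, -4.93 to -2.69; 201 and 8 UMIs, from 65 of 750 and 8 of 519 cells), as was Otx2 (-2.31), a factor of photoreceptors and bipolar cells that was higher in other cells than in Müller-like cells at both ages. Top2a, a mitotic topoisomerase, had 75 and 2 UMIs (-4.28, -7.35 to -2.37), 93.3% of the P14 UMIs being in 1 cell. Without Mki67 and Top2a, each with more than 50% of its UMIs in a single cell, 8 of 17 members were lower (median -0.38). The list percentile was 42.6 for members with at least 100 UMIs. Of 18 NFI and Notch pathway genes, 1 was higher and 8 lower (median -0.41, percentile 1.07). Hes6 (-1.80) and the helix-loop-helix inhibitors Id1 (-1.70), Id2 (-1.61) and Id3 (-1.35) were the members farthest from no change. Both lists kept a percentile below 2.5 in 11 of 14 alternatives.

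Lists that bear on nuclear position and on cell contacts stood close to other genes. Of 23 nuclear positioning genes, 2 were higher and 4 lower (median -0.16, percentile 22.7), led by Tubb2b, a tubulin of immature cells (-2.64), Syne3 (1.19), Lmna (-1.10) and Sun2 (1.10), the last 3 being genes of the nuclear envelope. Neither Syne3 nor Sun2 was at least 2 times as high in Müller-like cells as in all other P120 cells. In rod-like cells Syne3 was higher at P120 and passed that limit. Of 17 genes of the outer limiting membrane and adhesion, 2 were higher and 5 lower (median -0.20, percentile 19.98), with F11r at 2.32, Itga6 at -1.90, Crb2 at 0.89 (0.13 with doublets kept) and Dmd, which was more abundant in other cells, at -2.31. Of 9 Hippo pathway genes, 2 were higher and 1 lower (median 0.07, percentile 76.3), with Ccn2 at 1.56, Ajuba at 0.85, Wwtr1 at -0.67 and Tead1 at -0.54. The SoxE and Sox2 list had 3 measured members, 0 of them past 1.5-fold (median 0.39, percentile 89.2).

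Of 18 cholesterol and lipid genes, 11 were higher and 1 lower at P120 (median 0.86, percentile 100). The sterol sensor Insig1 (1.73) was higher. Fabp7, the fatty acid binding protein of immature glia, went from 328 UMIs to 0 (56.5-fold lower with P120 set at the floor of 3 UMIs). Only Srebf1 of the 11 was at least 2 times as high as in all other P120 cells. The list was also higher in rod-like cells (12 of 19, percentile 99.97) and amacrine-like cells (12 of 19, percentile 100). Of the 12 in each, 0 in rod-like and 9 in amacrine-like cells passed that limit. In bipolar-like cells 6 of 18 were higher and 0 of these passed it (median 0.35, percentile 99.0, but -0.99 with the ambient profile subtracted). Of 18 immediate early and dissociation stress genes, 1 was higher and 8 lower (median -0.55, percentile 0.210; below 2.5 in 13 of 14 alternatives), with Nr4a1 at -1.61, Dusp1 at -1.27, Socs2 at 1.30 and Klf2 at -2.80 (-5.92 to -0.81; 27 and 2 UMIs).

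Lists of rod and cone genes, which mark other cell types, were lower at P120 in Müller droplets, and further lists were compared there. Of 22 rod genes, 17 were lower at P120 (median -0.82, percentile 0), with Rp1 at -1.75, Abca4 at -1.48, Rcvrn at -1.39 and Guca1a, the member that was higher, at 1.19 (0.42 with doublets kept). Of 10 cone genes, 1 was higher and 5 lower (median -0.47, percentile 1.88; below 2.5 in 11 of 13 alternatives), with Cngb3 at -2.60, Pcdh15 at -1.32 and Thrb at -0.84. Among 8 photoreceptor stress genes, 3 were higher and 3 lower (median -0.40, percentile 8.20; 0.95 and percentile 99.8 with no minimum count), with Hspb1 at 2.02 (0.22 with separate clustering), Hk2 at 1.94, Fgf2 at 1.88 and Gadd45b at -1.83 (-5.29 with the ambient profile subtracted). Of 8 microglial activation genes, 3 were higher and 0 lower (median 0.34, percentile 96.4), with Lgals3 at 2.60, P2ry12 at 0.86, Apoe at 0.76 and Ctsd at -0.43. Apoe and Lgals3 were at least 2 times as high in Müller-like cells as in all other P120 cells. So was Fgf2 of the stress list. Of 13 mitochondrial transcripts, 5 were higher and 1 lower (median 0.29, percentile 97.0), led by mt-Atp8 (2.28), mt-Nd4l (2.10), mt-Nd5 (1.72) and mt-Nd6 (1.49). Of the 5 sex-linked transcripts, Xist was higher (506 and 789 CPM; 0.64) and 4 Y-linked genes lower, with Eif2s3y at -1.21, Uty at -0.97 and Kdm5d at -0.72. UMIs of Xist and of Y-linked genes were thus present in both libraries in different proportions (median -0.72, percentile 1.49; below 2.5 in 9 of 14 alternatives).

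**Figure D2:**
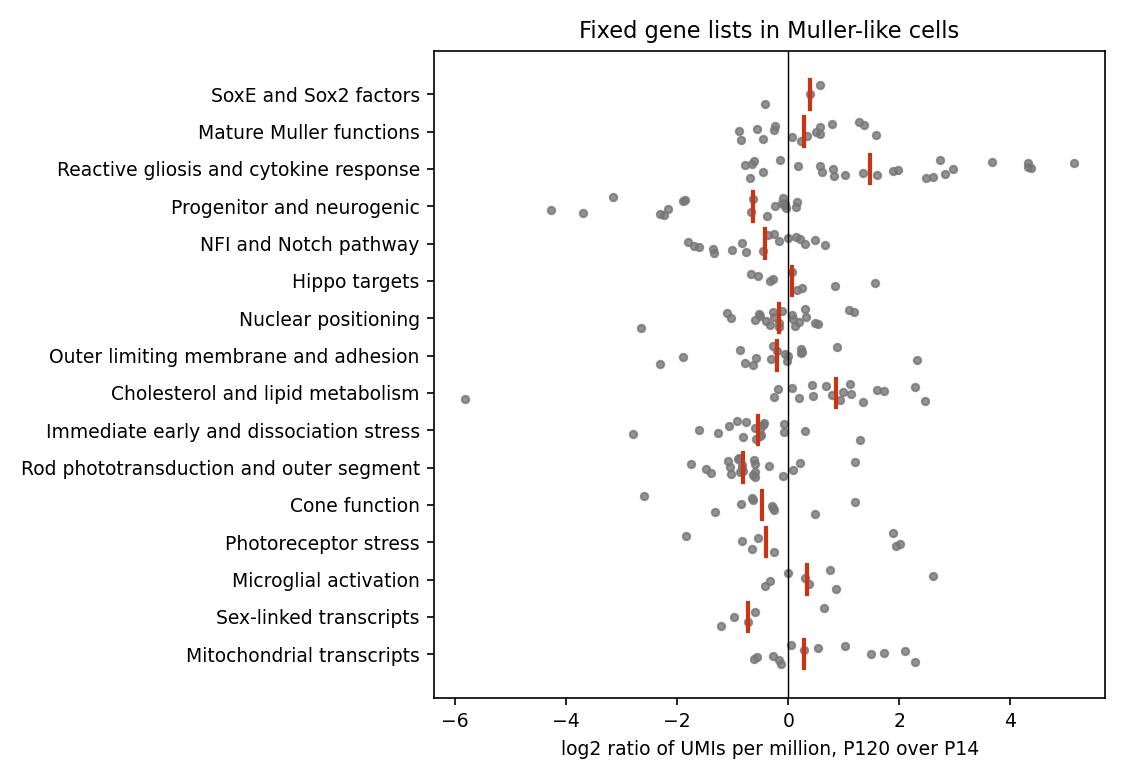
Log2 ratio of CPM, P120 over P14, in Müller-like cells for each measured member of the fixed gene lists (grey points; genes at 0 in a library are at their bound); red bars are list medians. The gliosis median is at 1.47 and the cholesterol median at 0.86, while the progenitor median is at -0.63.

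Among genes with at least 100 CPM that were at least 2 times as high in Müller-like cells as in all other cells, those with the highest P120 over P14 ratio were the histone gene Hist1h4h (3.25), Folh1, Mt2, the Rac exchange factor Prex2 (2.58), the iron carrier Trf (2.45), the sodium channel subunit Scn7a (2.35), Thrsp, a regulator of lipid synthesis (2.33), Pcolce2, a procollagen processing enhancer (2.16), Enho (2.13) and Ogfrl1 (2.07). Hist1h4h was at least 4-fold higher in rod-, cone-, bipolar- and amacrine-like cells too. The lowest ratios after Itm2a were those of the actin binding protein Tagln2 (-2.82), the collagen chain Col9a3 (-2.64), the fibrillin Fbn2 (-2.43), Btbd17 (-2.23), the interferon regulatory factor Irf1 (-2.03), Igfbp7 (-2.03), Hopx, the nuclear receptor Nr4a3 (-1.92) and Creb5 (-1.91). Age, animal and library cannot be separated in this comparison.

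In rod-like cells, rod phototransduction genes stood near other genes while stress genes were higher at P120. Of 22 rod genes, 3 were higher and 3 lower (median -0.12, percentile 55.2), with the cyclase activator Guca1a at 1.62, Slc24a1 at 0.72, Guca1b at 0.72 and Rcvrn at -0.89. Of 10 photoreceptor stress genes, 7 were higher and 0 lower (median 1.27, percentile 99.6). Edn2, an endothelin made by injured photoreceptors, was at 5.65 (4.32 to 7.33; 5 and 47 UMIs), the hexokinase Hk2 at 3.23 (3.14 to 3.32), the heat shock protein Hspb1 at 2.61 and Gadd45b at 2.27. Of the 7, only Edn2, Fgf2 and Hk2 were at least 2 times as high as in all other P120 cells. In the same droplets 10 of 15 genes of mature Müller functions were higher (median 1.01, percentile 99.93), as were 7 of 11 microglial activation genes (median 1.28, percentile 99.7). With the same limits applied to rod-like cells, at 100 CPM and 2 times all other cells, the highest ratios were those of the kinase Sgk1 (5.60), Dpp10 (5.25; 26.6 and 1014 CPM), 9330159M07Rik (5.13), AY036118 (4.56) and the collagen chain Col4a3 (4.23), and the lowest those of Ttyh2 (-3.47), Spry2 (-2.88), Lrp4 (-2.72), Trib1 (-2.49) and Kirrel (-2.39). Rod-like cells came from c0 and c1 at P14 and c6 and c41 at P120, with median depths of 5479 and 1004 UMIs.

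In cone-like cells, cone genes were higher and rod genes lower at P120. Of 13 cone genes, 10 were higher and 0 lower (median 1.04, percentile 100), with Guca1a at 1.38, Ccdc136 at 1.16, the transducin subunit Gnb3 at 1.13 and the channel subunit Cngb3 at 1.10. Of 22 rod genes, 1 was higher and 18 lower (median -1.31, percentile 0), with Pde6b at -3.38, Gnb1 at -3.27, Esrrb at -3.24 and Cnga1 at -3.17. The P14 cone cluster c2 had all 8 rod markers at least 2 times as high as in the rest of its library, and the P120 cluster c40 had 3. Of 9 photoreceptor stress genes, 4 were higher and 3 lower (median 0.44), and of 13 mitochondrial transcripts 8 were higher and 0 lower (median 0.72, percentile 99.95). Hist1h4c (2.79), A1bg (2.56), Hk2 (2.53), Gzmm (2.49) and Gem (2.39) had the highest ratios among cone-enriched genes of at least 100 CPM, and Gulp1 (-4.69), Nt5e (-4.23), Lrp4 (-3.99), the rod factor Nr2e3 (-3.87) and Insm1 (-3.76) the lowest.

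In bipolar- and amacrine-like cells, the progenitor and neurogenic list stood within the middle 95% of random lists (0 of 14 members higher and 6 lower in bipolar-like cells, percentile 5.44; 5 of 17 higher and 5 lower in amacrine-like cells, percentile 74.9). Among genes of at least 100 CPM enriched 2 times in bipolar-like cells, Sox4, a factor of differentiating neurons, was at -2.91 in bipolar-like cells, beside Sema5b (-3.34), Ppp1r14b (-2.51), Hopx (-2.34) and Kdm6b (-1.74). E130102H24Rik (2.66), Ano3 (2.56), the factor Mef2c (2.36), the GABA receptor subunit Gabra5 (2.23) and the potassium channel Kcnj9 (2.06) were the highest there. Among genes with the same limits in amacrine-like cells, Marcksl1 (-3.75), Tubb2b (-3.28), Crabp1 (-3.07), Nnat (-2.96) and Ttc9b (-2.00) were the lowest, and the noncoding or uncharacterised transcripts Grip1os2 (2.57), A330015K06Rik (2.38), 4930532I03Rik (2.09), 4930445B16Rik (2.09) and 1700111E14Rik (2.02) the highest. Many bipolar-like cells lay in clusters held wholly or mostly by a single age, such as c13 (366 cells at P14 and 0 at P120), c32 (191 and 0), c31 (20 and 254) and c39 (8 and 198). Gliosis genes were higher in bipolar-like cells (13 of 21, percentile 100, but 66.7 with the ambient profile subtracted). Immediate early genes, lower in Müller-like cells, were higher in bipolar-like (8 of 18, percentile 99.4) and amacrine-like cells (8 of 18, percentile 99.9). With the ambient profile subtracted those percentiles were 13.2 and 93.7. Mitochondrial transcripts were lower in amacrine-like cells (8 of 13, median -0.67, percentile 0) and higher in bipolar-like cells (5 of 13, median 0.43, percentile 99.92). Scaling by edgeR's TMM factor shifted all log2 ratios by -0.11 in rod-like and -0.12 in amacrine-like cells.

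Microglia-like cells, 91 at P14 and 74 at P120, had more immediate early RNA at P120 and less RNA of the microglial activation list. That list also holds genes of resting microglia, such as P2ry12 and Siglech, so its median does not give a direction of activation. Of 16 immediate early genes, 15 were higher and 0 lower (median 1.72, percentile 100), with Klf4 at 6.40 (4.50 to 9.47; 2 and 80 UMIs), Atf3 at 3.62 (3.19 to 4.07), Fosb at 2.64 and Jun at 2.41. Of 15 microglial activation genes, 1, Siglech (0.62), a gene of resting microglia, was higher and 7 lower (median -0.57, percentile 0.200; percentile 39.8 for members with at least 100 UMIs). P2ry12, a receptor of resting microglia, was at -1.24 (-1.53 to -0.96), Cst7 at -1.13 and Lpl at -2.17 (-5.32 to -0.12, 19 and 2 UMIs). Spp1 went from 22 UMIs to 0, or 3.48-fold lower with P120 set at the floor of 3 UMIs. In the same droplets 11 of 22 rod genes were higher and 0 lower (median 0.55, percentile 99.93), mitochondrial transcripts had a median of -0.56 (percentile 0.05), and the estimated ambient share was 32.3% at P14 and 88.0% at P120.

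Genes that differed at least 4-fold in the same direction in Müller-, rod-, cone-, bipolar- and amacrine-like cells numbered 12, all higher at P120. The largest mean log2 ratios were those of 6 genes of lens crystallins, at 9.14 or more, where 0 UMIs at P14 were set to the floor (Cryaa, Crybb2, Crygs, Cryba4, Cryba2 and Cryba1), followed by AY036118 (3.80), Hist1h4h (3.34), Hist1h4d (3.02) and Tsix (2.95). Each droplet of a retinal type at P120 held a mean of 17.2 to 20.9 crystallin UMIs, against 1440 in lens-like cells and 0.396 or fewer in the types of the P14 library.

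**Figure D3:**
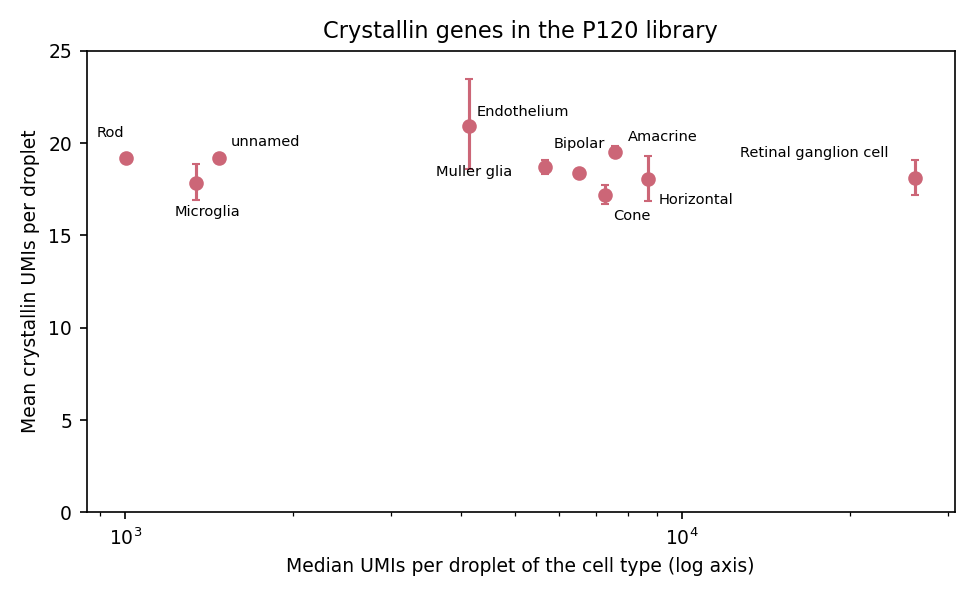
Mean crystallin UMIs per droplet (sum of 6 genes, exact Poisson 95% intervals) against the median UMIs per droplet (log axis) of each retinal cell type in the P120 library. The means lie between 17.2 and 20.9 while the median depth runs from 1004 in rod-like to 26195 in ganglion-cell-like cells.

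In the multiome data, the feature list held 195822 ATAC peaks with a median length of 884 bases (189 to 2404), covering 169 Mb. Of these peaks, 191251 lay on the 19 autosomes. Near Sox8 (chromosome 17, 25565893 to 25570686) 6 peaks lay within 5 kb, and 2 overlapped the gene, at 25567774 to 25568643 and 25570321 to 25571241. Near Sox9, 3 peaks lay within 5 kb, of which 112781656 to 112782557 and 112784631 to 112785552 overlapped the gene and 112779484 to 112780333 lay outside it. Within the same distance, Slc1a3, the glutamate transporter, had 24 peaks, the potassium channel Kcnj10 11, the retinoid carrier Rlbp1 9, Gfap 7, Aqp4 5, Sox10 5, Sox2 3 and Glul 2. These counts are not scaled to gene length, with windows from 12467 bases for Sox2 to 86684 for Slc1a3. Peaks covered 32.3% of the window of Sox8, 29.9% for Gfap, 27.4% for Rlbp1, 23.2% for Slc1a3, 20.9% for Kcnj10, 17.2% for Sox9 and 9.13% for Glul. The list names no sample and gives no value per library, so whether it covers both genotypes is not known. Accessibility in Sox8/9 cKO and control nuclei was therefore not compared. The list does not say whether starts count from 0 or 1. Within 50 kb the counts were 30 for Sox8 and 14 for Sox9.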

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

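The multiome peak list holds 1 peak on the GFP sequence, from 1657 to 2098, a length of 441 bases. It was picked out because it lies in data that no comparison between groups uses, and its length is not a count. The titles of both P17 groups name Sun1GFP and GFP+, so a GFP sequence in these nuclei is part of the design. No explanation of it was tested, and every choice here was made after the list was seen.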

How the results depend on the processing

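The added alternatives, without the low-depth Müller cluster and with no check of single cells, were chosen after the data were seen; the others were planned. Of 358 alternative values of 31 main results, 304 stayed within the counting or resampling interval, 52 moved out of it and 2, of results outside the middle 95% or with an interval excluding 0, changed sign; of 4692 values of 408 named genes, 4228, 450 and 14 did; and of 793 values of 70 lists in other cell types, 761, 25 and 7 did. Sign changes of results without such a call are not counted as such. Gliosis and cholesterol medians of Müller-like cells stayed above the middle 95% of random lists in 14 of 14 alternatives. The alternatives that only rescale the totals are among the 14 and could not have changed this. No paired analysis was possible because each group has 1 sample. Unless the setting itself shows it, the cause was not tested.

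With no cell filter, Sox9 in Müller-like cells was at 457 CPM (P14) and 393 CPM (P120) with a log2 ratio of -0.22, the Müller share at P120 was 4.44%, and list medians were -0.42 (immediate early) and -1.33 (rod). With the strict filter Sox9 was at 394 CPM at P14 and a ratio of -0.0511, Sox8 and the SoxE list at 0.69, and medians at -0.39 (immediate early), -1.26 (rod), -1.12 (cone) and, for cone genes in cone-like cells, 1.11. With doublets kept Sox9 was at 325 and 328 CPM and a ratio of 0.0118, Sox8 and the SoxE list at 0.76, and medians at -0.30 (immediate early) and -1.25 (rod); the rod list was at -0.0745 in bipolar-like and -0.35 in amacrine-like cells. With separate clustering Sox9 was at 432 and 399 CPM and a ratio of -0.12, seen after thinning in 30.6% of cells at P120; the Müller share at P120 was 4.14%, Sox8 and the SoxE list at 0.64, the mature list at -0.0213, the rod list at -1.12 and Ptgds at -0.57. In rod-like cells that setting put the progenitor list at -0.18, Sox9 at -0.81, Sox2 at -0.33, Nfia at -0.20, Maml2 at -0.0686 and Ccn1 at -0.0003. At resolution 0.5 Sox9 was at 412 CPM (P14) and a ratio of -0.18, Sox8 at 0.60, the SoxE list at 0.58 and the rod list of rod-like cells at -0.22, and at resolution 2.0 Sox9 was at 457 CPM and -0.31, the Müller share at P14 at 7.05% and the rod list at -1.17. Without the low-depth cluster Sox9 was at 547 and 399 CPM, seen in 36.4% and 30.8% of thinned cells, and the rod list at -1.14. Thinning to 2000 UMIs gave Sox9 shares of 43.1% and 37.8%, and no thinning 42.3% and 51.8%; deeper thinning also leaves out more shallow cells. The TMM factor put the rod list of rod-like cells at -0.23.

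Subtracting the ambient profile put Müller medians at -0.91 (immediate early) and -3.90 (rod). Since rod genes set the share subtracted, values of the rod list under this setting say nothing about a change. In bipolar-like cells it put the mature Müller list at -0.44, cholesterol at -0.99, immediate early genes at -0.35, S100a6 at -1.20, Notch2 at -1.01, Syne3 at -0.52 and Insig1 at -0.96, and in amacrine-like cells the rod list at -0.68, Sox9 at -1.12, Ptgds at -4.37, Guca1b at -1.10 and Hk2 at -1.84. Within 50 kb, 30 peaks lay near Sox8 and 14 near Sox9, and 2 inside Sox8, by the wider or narrower window. Depth limits the genes of microglia-like cells most, with 236164 UMIs at P120 and 5464 genes at the minimum, against 13692 in Müller-like and 13791 in cone-like cells.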

Other observations

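All tests below were chosen, in the form given, after a result was seen. That of Sox8 in cells without Sox9 had been set beforehand on fewer cells, where it argued against higher Sox8, and its cells and those of the test of Sox9 spread were then widened. Among bipolar clusters, the Sox9 level was highest in c29 at P14 (169 CPM, 150 to 191; 117 cells) and c39 at P120 (122 CPM, 103 to 143; 198 cells), both led by Otor, Grik1 and Gsg1, the last 2 being markers of OFF cone bipolar cells. At P14, c22 held more Sox9 UMIs than c29 (418 against 263) at a lower level (42.0 CPM; 256 cells). The rod bipolar clusters, led by Pcp2, Trpm1, Car8, Prkca and Sebox, held 1.86 CPM (c13, P14) and 0.487 CPM (c31, P120). Müller genes were low in c29 and c39, with Glul at 67.6 and 101 CPM and Rlbp1 at 14.8 and 12.2 CPM. A small cluster, c37, led by Optc, Crhbp and Gfap with markers of both astrocytes and Müller glia, held 99.0 and 203 CPM of Sox9.

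A low-depth Müller cluster held 400 of the P14 and 207 of the P120 Müller-like cells, at medians of 1197.5 and 1045 UMIs against 15457.5 and 10316.5 in the other Müller-like cells. Against these, the nuclear RNA Malat1 was at -2.61 and -2.16 on the log2 scale at P14 and P120, the imprinted noncoding RNA Kcnq1ot1 at -3.89 and -2.70, Nfia at -2.32 and -2.45, and Sox9 at -3.56 and -2.31 (46.5 against 547 CPM and 80.5 against 399 CPM). Sox8 was at -0.34 and -0.80, Sox2 at -0.77 and -1.14, Hes1 at -0.34 and -1.18, Glul at -0.08 and -0.55, Rlbp1 at 0.52 and -0.13, and Lhx2 at 0.13 and -0.26.

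Crystallin UMIs in every retinal type at P120 may be free RNA of lens cells. Droplet means of the retinal types differed by at most 1.22 times, and Cryaa made up 25.9% to 30.5% of the crystallin UMIs in each type, against 34.7% in lens-like cells. Expression in the retinal cells themselves is argued against, since ganglion-cell-like droplets held 0.943 times the crystallin UMIs of rod-like droplets at 26.1 times the depth. Which step brought lens tissue into the P120 sample was not tested, and genes that lens cells share with glia may be raised in the same way.

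Sox9 RNA in Müller-like cells of both cKO libraries was not explained by free RNA, as these droplets held 292 times the Sox9 UMIs of rod-like droplets at P14 and 395 times at P120. Whether cells with and without Sox9 RNA were mixed could not be told, as Sox9 passed the 95th percentile of genes of like mean at P120 only. Its variance over the mean was 4.27 at P14 (percentile 91.8, limit 5.17) and 3.68 at P120 (percentile 98.2, limit 2.31). Of deep cells thinned to 5000 UMIs, 74 of 293 (25.3%) lacked a Sox9 UMI at P14 and 82 of 265 (30.9%) at P120. A Poisson count gives 4.37% and 13.4%, but genes of like mean also spread more than that (median 1.63 and 1.24). The low-depth Müller cluster was left out of this test. Whether Sox8 is higher in the cells without a Sox9 UMI could not be told, with ratios of 1.21 (0.836 to 1.73) and 0.861 (0.617 to 1.19). Incomplete deletion and transcripts that lack the floxed part but keep the 3' end both stay open.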
